A study of Mus musculus with 16 samples.

How the data were processed

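Poly(A)-selected, strand-specific RNA sequencing was carried out on mouse embryo fibroblasts (MEFs) that carried or lacked Arkadia, the RING-domain ubiquitin ligase encoded by Rnf111, before and after stimulation with TGFβ at 2.5 ng/ml. The 16 libraries came from 4 lines: wild-type MEFs (WT), Arkadia-deficient MEFs (null), and null MEFs infected with a retrovirus carrying wild-type Arkadia (rvWT) or Arkadia mutated in its SUMO-interacting motif (sim). The design text names 2 sequencing batches. The library names put 8 libraries in a set A (WT and null at 0, 1, 4 and 16 h) and 8 in a set B (rvWT and sim at 0, 1 and 4 h, null at 0 and 1 h). Apart from null at 0 and at 1 h, which had 1 library in each set, each line had 1 library per time. Replicates within a line and time were therefore almost absent, and the times of a line served as its repeated measurements. Nothing in the labels says how many separate cultures stand behind the libraries, so the p-values measure the spread between these libraries, which may be technical in part. No library of an empty retrovirus was part of the series as used here.

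The authors deposited 1 table of FPKM values (fragment counts scaled to transcript length and to mapped fragments). Per the submitters' processing notes the tools were CASAVA 1.8.2, STAR 2.3.0e, SAMtools and Cufflinks 2.2.1 with genome build mm9, with no order or role given; the annotation, the treatment of reads that map to several places and the normalization option are not given in the sources used here. The table held 12100 genes, each under 1 symbol and 1 RefSeq transcript accession, of which 11458 were coding (NM) and 642 non-coding (NR). No gene had a mean under 0.25 FPKM in either set, so genes silent in a set are not seen. Set B holds no WT library. A gene on in WT and silent in the lines of set B is therefore absent, while a gene silent in WT can be present through null. Because 2631 entries were named as a transcript variant, a gene's value can be that of a single isoform. Exact 0 values were not always true absences: Drosha, which every cell uses, was listed at 0 in the WT 0 h and null 16 h libraries and at 23.4 to 36.6 FPKM in the others. In 334 genes the value lay under 0.1 FPKM in a library and at 5 FPKM or more in another. Small RNAs (136 symbols for microRNAs, small nucleolar and Cajal body RNAs), which poly(A) libraries capture poorly, held 4.98% to 8.78% of the FPKM of a library. The available reference was of a newer build than mm9 and no coordinates are given.

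The total FPKM per library ran from 397019 to 481970. Read depth is unknown: the low values did not fall on whole multiples of a common step (at the best offset 70 of 243 genes under 0.25 FPKM in the WT 0 h and 1 h libraries had a whole-number ratio within 0.006 on the log2 scale), so no count of reads could be recovered and no counting interval is given. The scatter between libraries is the sole measure of precision.

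Values were analysed as log2(FPKM + 1) after a filter of a mean of at least 1 FPKM over the libraries of a fit; differences on this scale understate the change of genes with low values. The test was limma 3.58.1 (limma-trend, R 4.3.3, statmod 1.5.0) with Benjamini-Hochberg adjustment over the genes tested and an adjusted p below 0.05. Line differences were fitted with time as a block: WT against null over the 8 libraries of set A, and rvWT, sim and null over the 8 libraries of set B. The TGFβ response at 1, 4 and 16 h was fitted over all 16 libraries with the 5 time series (WT, null of set A, null of set B, rvWT, sim) as a block. Differences in the response by Arkadia status were fitted in the same way with terms for treatment by status. Gene lists (26, of signalling targets, matrix, cell cycle, stress and metabolic genes, chromatin complexes and markers of other cell types) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and 25 of them had enough tested members for a test. Medians of gene lists were set against 10000 random lists matched on mean expression.

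Named genes followed a rule: Rnf111 in every library; for each comparison the 10 largest rises and 10 largest falls among genes that passed, reached 5 FPKM on the higher side and moved the same way in every time-matched pair or series; up to 4 members of each list with the smallest p; where no gene passed, the 5 with the smallest p each way; and the largest WT minus null differences in the 4 h and 16 h responses. The designs, lists, this rule and the alternatives were set before the data were examined, except where a later choice is named. The alternatives were pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, median-ratio and quantile scaling, limma without trend or with robust variances, an added log2 threshold of 1, other model terms, each set alone, and each library left out in turn. Another 3 alternatives (without small RNAs, without small RNAs and the 334 genes that drop out, and without the 16 h libraries) were chosen after the data had been seen.

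The code was tested on simulated data made from the real gene means and spreads with 200 changed genes in each of 5 runs. For WT against null, 56.7% of genes changed by 0.5 on the log2 scale, 87.8% of those changed by 1 and 92.1% of those changed by 2 were recovered; for rvWT against sim the values were 64.2%, 89.9% and 96.4%. For the TGFβ response they were 80.3%, 95.2% and 98.2% at 1 h, and 62.4%, 89.9% and 96.1% at 16 h. For the difference in response between wild-type Arkadia and null they were 28.1%, 77.6% and 93.9%, and for that between sim and null 17%, 59.1% and 88.8%. Both rvWT and sim were compared with the same null libraries. In 100 simulations unchanged lines were set against those libraries, which gave the correlation that the shared control alone produces. Lines that change independently of each other were not simulated. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15). Results for 5 genes withheld for evaluation are not reported here; they stayed in the tests and counts.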

Results

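RNA was measured in 16 libraries of mouse embryo fibroblasts (MEFs) with 4 states of Arkadia, a ubiquitin ligase of the TGFβ pathway encoded by Rnf111. WT and null MEFs were sampled at 0, 1, 4 and 16 h of TGFβ (set A, 8 libraries). Null MEFs that had received wild-type Arkadia (rvWT) or Arkadia with a mutated SUMO-interacting motif (sim) by retrovirus were sampled at 0, 1 and 4 h, beside null MEFs at 0 and 1 h (set B, 8 libraries). The table gives FPKM for 12100 genes with no read counts, so the depth of each library is unknown. The median Spearman correlation across genes, which are not independent replicates, was 0.970 for the 19 pairs within a series, 0.970 for the 9 pairs of rvWT with sim and 0.962 for the 2 pairs of null libraries of sets A and B at the same time. It was 0.936 for the 36 pairs of null with rvWT or sim and 0.873 for the 48 pairs of WT with another line. Pairs across sets and times are included in both of these groups. The 6 pairs of null libraries across sets at other times had a median of 0.949.

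The level of Rnf111 followed the labels in every library. Its mean was 14.8 ± 0.306 FPKM in WT (SD, n = 4) and 0.163 ± 0.0331 in null cells of set A (SD, n = 4), with 0.481 ± 0.0646 in null cells of set B (SD, n = 2). It reached 112.8 ± 11.9 FPKM in rvWT (SD, n = 3) and 59.7 ± 3.31 in sim (SD, n = 3), both above the WT level. Xist, the RNA that coats the inactive X chromosome in female cells, was at 2.31 ± 0.402 FPKM in WT (SD, n = 4). It was at 48.8 ± 1.86 FPKM in null cells of set A (SD, n = 4), 34.5 ± 0.234 in null cells of set B (SD, n = 2), 33.0 ± 10.7 in rvWT (SD, n = 3) and 33.4 ± 6.56 in sim (SD, n = 3).

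**Figure D1:**
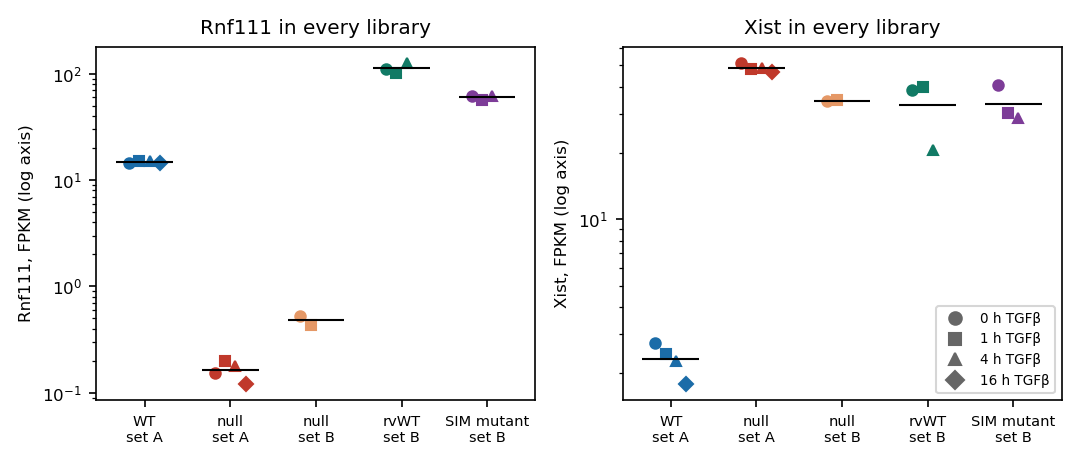
FPKM of Rnf111 (left) and Xist (right) on log axes, with 1 point per library, the symbol giving the hours of TGFβ and the horizontal line the mean of a series. Rnf111 lies near 14.8 FPKM in WT, under 1 FPKM in null and above the WT level in rvWT and sim, while Xist lies near 2.31 FPKM in WT and at 20.7 FPKM or more in every other library.

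WT and null MEFs were compared over 4 time points each to find the genes whose level differs with Arkadia. Krt19, a keratin of simple epithelia, was the most elevated named gene in WT, at 408.1 ± 130.2 FPKM against 3.44 ± 1.71 in null (SD, n = 4 each; log2 difference 6.56 ± 0.06 SE, limma adjusted p = 4.02e-06). The iron carrier Trf (log2 difference 5.995), the transcriptional coactivator Eya4 (4.65), the desmosomal protein Pkp1 (4.05) and the lymphatic growth factor receptor Flt4 (4.00) were higher in WT too. S100a4, a calcium-binding protein of fibroblasts, stood at 75.1 ± 9.08 FPKM in WT against 2562 ± 526 in null (log2 difference -5.06 ± 0.11 SE, adjusted p = 1.82e-05). The collagen Col3a1 stood at 9.20 ± 1.77 against 320 ± 33.8 FPKM (-4.98 ± 0.13 SE, adjusted p = 2.49e-05), and the secreted proteins Ptn (-5.84), Sfrp1 (-5.46), Postn (-5.33) and Igfbp3 (-4.83) were lower in WT as well. Cd200 (4.71), Slc38a4 (4.18), Lmcd1 (4.00) and Btc (3.81) were also among the largest elevations, and Arhgdib (-5.68), Cck (-5.19) and Fxyd6 (-5.01) among the largest reductions. The microRNA genes Mir3061 (4.32) and Mir196a-1 (-7.66) passed as well, the latter listed at 0 in the 4 WT libraries. The difference of Mir3061 ran from 0.208 to 7.115 over the time-matched pairs. Of 10976 genes tested, 7411 passed (67.5%), 4105 higher and 3306 lower in WT (3621 and 3620 with median-ratio scaling), and 1336 of them differed by at least 1 on the log2 scale (499 higher, 837 lower). Genes on in WT and silent in set B are absent from the values, so these counts can be tilted toward genes lower in WT. Each line is represented by its own cells, so line and Arkadia status cannot be told apart here, and Xist itself differed by -3.92 ± 0.07 (SE, adjusted p = 1.20e-05).

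Fixed gene lists showed which groups differed between WT and null, beside the Xist difference of -3.92. List members on in WT and silent in set B were not measured, so the shares lower in WT can be too high. Hox genes, which encode positional transcription factors, were lower in WT in 17 of 18 cases with 1 not passing, the same adjusted over the list alone, and Hoxb6 (-3.41), Hoxb9 (-2.41) and Hoxd8 (-2.11) are examples. For Hox genes camera gave adjusted p = 2.26e-06, and adjusted p = 0.479 with an estimated correlation. Fibroblast markers were lower in 9 of 10 cases (9 adjusted over the list alone), among them the collagen receptor Ddr2 (-2.08), Ly6a (-3.71) and Cd34 (-4.54). For fibroblast markers camera gave adjusted p = 7.46e-05, and adjusted p = 0.326 with an estimated correlation. Genes of hypoxia and glycolysis were lower in 15 of 18 cases, or 16 adjusted over the list alone, with the lactate dehydrogenase Ldha at -1.55, the prolyl hydroxylase P4ha1 at -1.67 and Pgk1 at -0.94. For the hypoxia list camera gave adjusted p = 4.46e-06, and adjusted p = 0.455 with an estimated correlation. Of 21 genes of cholesterol synthesis 15 were lower and 1 higher (the same adjusted over the list alone), with Sqle at -1.47 and Insig1 at -1.16. For cholesterol synthesis genes camera gave adjusted p = 0.000988, and adjusted p = 0.739 with an estimated correlation. Of 34 extracellular matrix genes 18 were lower, 6 higher and 10 did not pass (18 and 6 adjusted over the list alone), with Loxl3 at -1.92, Mfap5 at -2.58 and Col1a2 at -1.33. For matrix genes camera gave adjusted p = 0.00989, and adjusted p = 0.638 with an estimated correlation. Of 17 interferon response genes 11 were lower and 2 higher, the same adjusted over the list alone, including Oas1a (-1.98), Ifit1 (-1.79) and B2m (-0.92). Of 13 imprinted genes 10 were lower and 2 higher, the same adjusted over the list alone, with Dlk1 at -4.20, Peg10 at -3.30 and the growth-factor adaptor Grb10 at 2.37. For both of these lists the camera adjusted p was 0.00409, and adjusted p = 0.326 with an estimated correlation. Replication-dependent histones were lower in 6 of 7 cases, the same adjusted over the list alone (camera adjusted p = 0.00851; adjusted p = 0.326 with an estimated correlation), with Hist1h1c at -1.67. The FPKM values covered 39 such genes, so most lay under the filter of a mean of 1 FPKM in set A.

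Camera called none of the remaining lists between WT and null (counts adjusted over the list alone were the same except where given). Of 21 early TGFβ targets 8 were higher and 4 lower, with the TGFβ feedback inhibitor Pmepa1 at 1.33 and the matrix protein Tgfbi at -2.72. Of 12 BMP and Id targets 2 were higher and 4 lower (4 and 3 with quantile normalization), with the BMP antagonist Grem1 at -4.22. Of 20 contractile genes 7 were higher, such as Cnn1 (2.10) and Tagln (1.83), and 8 lower, such as Myl9 (-3.87). Of 23 receptors, SMADs and ligands 6 were higher and 9 lower, with the co-receptor Tgfbr3 at -2.00. Polycomb subunits were higher in 16 and lower in 7 of 31 cases (12 and 8 after median-ratio scaling), with the methyltransferase Ezh2 at 0.59. SUMO pathway genes were higher in 8 and lower in 3 of 19 cases (8 and 5 after median-ratio scaling), with the protease Senp3 at 0.84. Cell cycle genes were higher in 14 and lower in 5 of 28 cases (15 and 5 adjusted over the list alone), with Mcm2 at 0.83 and cyclin D1, Ccnd1, at -3.28. Immediate early genes went 8 up and 9 down of 21, p53 targets 4 up and 7 down of 17, and cytokines, chemokines and proteases 5 up and 13 down of 23, the latter with the gelatinase Mmp2 at 3.34. The median and mean were -0.07 and 0.03 for immediate early genes, and 0.12 and 0.04 for p53 targets, for which camera pointed down. Among markers of other cell types, Krt7 (-2.51) and Krt8 (-1.87) were lower while Krt19 was higher. Kdr (-1.79) was lower and Flt1 (1.53) higher among endothelial markers, Cd14 (-1.70) lower and Cd68 (0.96) higher among haematopoietic ones. The neural markers Nes (1.60), Tubb3 (1.22) and Ncam1 (0.60) and the cartilage and bone markers Spp1 (0.56) and Sox9 (0.61) were higher, the adipocyte marker Lpl (-1.39) was lower, and the muscle markers Acta1 (-0.17) and Mylpf (0.32) did not pass. Fry, which asks whether a list moves on balance one way without comparing it with other genes, called 17 of 25 lists between WT and null. Among the lists of this paragraph it pointed down for BMP and Id targets (adjusted p = 0.00775), receptors, SMADs and ligands (0.00171), endothelial (0.00523) and adipocyte markers (0.00123). It pointed up for Polycomb subunits (adjusted p = 0.0299), SUMO pathway genes (0.0219), neural markers (0.00101), cartilage and bone markers (0.00755) and epithelial markers (0.000971; median -0.553, mean 0.475).

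**Figure D2:**
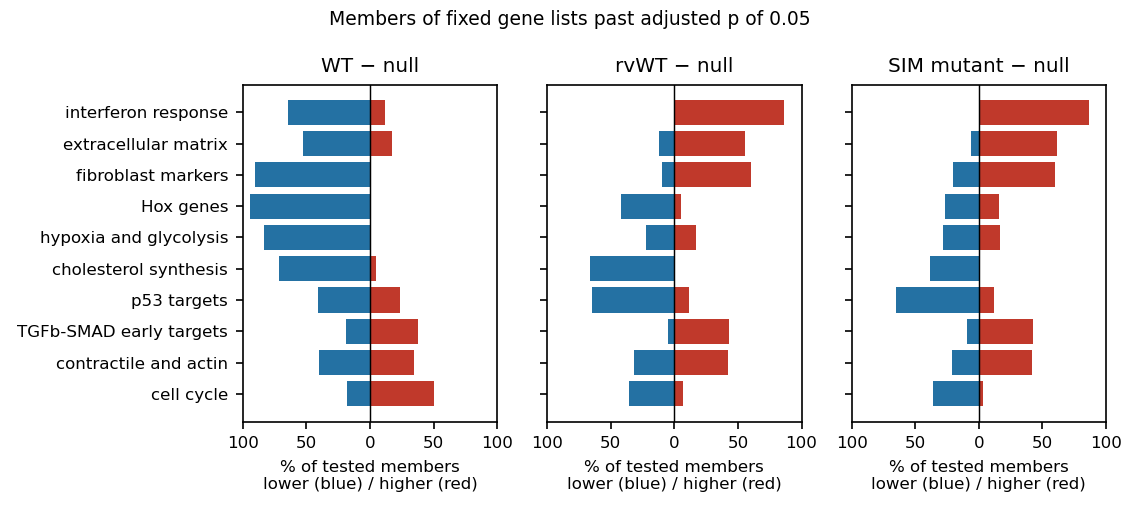
Percent of the tested members of 10 gene lists that passed an adjusted p of 0.05, lower (blue, to the left) or higher (red, to the right), for WT minus null, rvWT minus null and SIM mutant minus null. Hox genes were lower in 17 of 18 cases in WT, and interferon response genes were higher in 19 of 22 cases in both retroviral lines.

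Reconstituted lines, which received Arkadia, wild-type or mutated in its SUMO-interacting motif, by retrovirus, were compared with null cells of set B. The null cells carried no retrovirus and no empty retrovirus was used here, so infection and Arkadia cannot be told apart in these differences. Rnf111 mRNA also exceeded the WT level in both lines. Besides Rnf111 (6.21 ± 0.06 SE in rvWT and 5.31 ± 0.06 SE in sim), the cell adhesion protein Cdsn was higher, at 97.4 ± 7.602 FPKM in rvWT (SD, n = 3) against 2.15 ± 0.307 in null (SD, n = 2), a log2 difference of 5.04 ± 0.07 (SE, limma adjusted p = 1.44e-05), and 4.05 ± 0.07 (SE) in sim. Postn, a matrix protein, was 3.24 ± 0.05 (SE) higher in rvWT (adjusted p = 2.03e-05) and 3.88 ± 0.05 (SE) higher in sim (adjusted p = 1.49e-05). The stress-induced pseudokinase Trib3 was higher by 2.85 and 2.67. The peptide hormone Cck (-4.40 in rvWT, -4.30 in sim), the stromelysin Mmp3 (-4.12 and -3.63), the tetraspanin Tspan8 (-2.96 and -2.95) and the adhesion molecule Bcam (-2.97 and -2.65) were lower in both lines. In rvWT the largest elevations also held Prl2c4 (2.89), Col6a3 (2.67), Prl2c2 (2.53), Krt14 (2.41) and Cox6a2 (2.37), and the largest reductions the complement regulator Serping1 (-2.88) and Scel (-2.86). Reads of the near-identical Prl2c2 and Prl2c4 can be shared, so their values are uncertain. In sim they held Aspn (2.77), Nov (2.46) and Dpysl3 (2.31). Small RNA genes passed as well, with Mir3061 (-4.71) and Snora47 (-3.34) lower in both lines, Snord87 (6.74) higher in rvWT, Mir1892 (8.36), Snord123 (4.59) and Mir1905 (2.303) higher in sim, and Snord52 (-10.66), Snord2 (-7.82), Mir1901 (-7.66) and Mir3074-1 (-6.26) lower in sim. Such values can drop out within a line. Snord87, listed at 0 in null of set B, stood at 254.3 FPKM at 0 h and at 0 at 4 h in null of set A, so its call is uncertain. Of 10958 genes tested, 4230 passed in rvWT (1756 higher, 2474 lower) and 3807 in sim (1528 higher, 2279 lower); with median-ratio scaling the splits were 2216 higher and 2045 lower, and 1946 higher and 1901 lower, and with quantile normalization 2414 and 2035, and 2143 and 1952. At least 1 on the log2 scale was reached by 651 and 555 genes. The rvWT count was 1946 without the null 0 h library of set B, 2006 without null 1 h, 2595 without rvWT 0 h and 2703 without rvWT 1 h, and the sim count 1581 without null 0 h, 1730 without null 1 h and 2304 without sim 0 h.

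Gene groups were followed in both reconstituted lines against null, and counts adjusted over the list alone were the same except where given. Interferon response genes were higher in 19 of 22 cases and lower in 0 in both lines (19 and 20 higher adjusted over the list alone), with the immunoproteasome subunit Psmb8 at 2.05 in rvWT and 1.82 in sim and Ifi44 at 1.75 and 2.26. For interferon response genes camera gave adjusted p = 1.52e-09 and 1.71e-11, and adjusted p = 0.282 and 0.368 with an estimated correlation. Of 34 extracellular matrix genes 19 were higher and 4 lower in rvWT (20 and 4 adjusted over the list alone), and 21 higher and 2 lower in sim (21 and 3). Col1a2 (1.84 and 1.61), Bgn (1.54 and 1.53) and Fbn1 (1.86 and 1.76) are examples (camera adjusted p = 4.24e-05 and 4.88e-07; adjusted p = 0.282 and 0.368 with an estimated correlation). Of 10 fibroblast markers 6 were higher and 1 lower in rvWT (8 and 1 adjusted over the list alone), and 6 higher and 2 lower in sim (7 and 2), with Prrx1 at 1.34 and 1.48 and Cd34 at -2.07 and -1.76. For fibroblast markers camera gave adjusted p = 0.00685 and 0.0277, and adjusted p = 0.282 and 0.368 with an estimated correlation. Early TGFβ targets were higher in 9 and lower in 1 of 21 cases in rvWT (the same adjusted over the list alone), and higher in 9 and lower in 2 in sim (9 and 3), including Tgfbi (1.88 and 1.84) and Snai1 (0.85 and 0.72). Their camera adjusted p was 0.00424 and 0.014, and adjusted p = 0.282 and 0.368 with an estimated correlation. Cholesterol synthesis genes were lower in 14 of 21 cases in rvWT (15 adjusted over the list alone) and in 8 in sim (11 lower and 1 higher adjusted over the list alone; 6 lower and 2 higher after median-ratio scaling), with Insig1 at -0.55 and -0.48. For cholesterol synthesis genes camera gave adjusted p = 0.000241 and 0.014, and adjusted p = 0.282 and 0.368 with an estimated correlation. Among 17 p53 targets 11 were lower and 2 higher in both lines (11 and 2, and 12 and 3, adjusted over the list alone), with Perp at -2.28 and -1.90 and the cell cycle inhibitor Cdkn1a at -1.27 and -1.61 (camera adjusted p = 0.0441 and 0.0182; adjusted p = 0.557 and 0.448 with an estimated correlation). Replication-dependent histones were lower in 8 of 25 cases in both lines (9 in sim adjusted over the list alone), with Hist1h4i at -0.93 and -0.94. For histone genes camera gave adjusted p = 0.041 and 0.014, and adjusted p = 0.557 and 0.368 with an estimated correlation. Cell cycle genes were lower in 10 of 28 cases in both lines and higher in 2 and 1 (7 lower and 4 higher in rvWT after median-ratio scaling), with Rrm2 at -0.83 and -0.74, and camera called the list in sim alone (adjusted p = 0.019; adjusted p = 0.368 with an estimated correlation). Camera called no other list in either line. Hox genes were higher in 1 and lower in 8 of 19 cases in rvWT, with Hoxa11 at -1.82, and higher in 3 and lower in 5 in sim (4 and 7 adjusted over the list alone; 5 and 4 after median-ratio scaling). Polycomb subunits were higher in 4 and lower in 3 of 31 cases in rvWT (2 and 3 adjusted over the list alone; 5 and 2 after median-ratio scaling; median -0.03 while camera pointed up), with Rybp at 0.77, and higher in 4 and lower in 6 in sim. Of 19 SUMO pathway genes 0 were higher and 3 lower in rvWT (2 lower adjusted over the list alone; 1 and 2 after median-ratio scaling), with Pias1 at -0.40. In sim 1 was higher and 3 lower (0 and 2 adjusted over the list alone; 3 and 2 after median-ratio scaling). Immediate early genes were higher in 9 and lower in 7 of 20 cases in rvWT, and higher in 4 and lower in 7 in sim (5 and 7 adjusted over the list alone). Of 23 receptors, SMADs and ligands 3 were higher and 9 lower in rvWT (4 and 9 adjusted over the list alone), and 5 higher and 7 lower in sim (6 and 8). Fry called 21 of 25 lists in rvWT and 16 in sim, pointing down for Hox genes (adjusted p = 0.00707 and 0.0411) and for immediate early genes (0.00601 and 0.00235; in rvWT their median was 0.243 and mean -0.099). For SUMO pathway genes and for receptors, SMADs and ligands it pointed down and called the lists in rvWT (adjusted p = 0.0162 each) and not in sim (0.139 each), and it called Polycomb subunits in neither line (0.506 and 0.297). Among markers of other cell types Krt7 (-1.89 and -1.56) and the endothelial receptor Kdr (-1.58 and -1.24) were lower and Krt14 (2.41 and 1.43) and the cartilage regulator Sox9 (1.71 and 1.27) higher. Beside these groups, 13 of 13 tested mesothelial markers, a list written after several of its values had been seen, were lower in both lines, among them the uroplakin Upk3b (-2.68 and -2.24) and Msln (-2.49 and -2.23).

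The changes in rvWT and in sim shared most genes, with 1282 higher and 2024 lower in both lines, against 244.9 and 514.5 for independent lists. Postn, Cdsn, Cck and Mmp3 were among them. Both lines were compared with the same null libraries, and unchanged lines simulated against them gave 0.01 shared genes on average. Unchanged lines yield few calls of any kind, so that number is no baseline for the overlap. Lines that change independently of each other against shared controls were not simulated. The correlation of the log2 differences was 0.864 (0.632 simulated, at most 0.747) and their covariance 0.279 (0.0606 simulated). The null group of set B has 2 libraries and could not be split, so part of the excess may come from the shared controls. Both lines were also infected, which cannot be told apart from Arkadia here.

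Genes that differ between WT and null were followed into rvWT, to see how far they lie toward the WT level there. These comparisons share no library, and rvWT differs from null by infection as well as by Arkadia. Cck, Tspan8 and Mmp3 were among the 972 genes lower than null in WT, rvWT and sim, while 516 genes were higher than null in all 3. Postn (-5.33 in WT and 3.24 in rvWT), Cdsn (-1.36 and 5.04) and Bcam (1.04 and -2.97) differed from null in opposite directions. Of 3897 genes higher in WT, 736 were higher in rvWT than in null (612.6 for independent lists) and 596 lower (887.1), and their median was 0.037 (95% of matched random lists from -0.041 to -0.023). Of 3278 genes lower in WT, 1143 were lower in rvWT (746.2 for independent lists) and 545 higher (515.3), with a median of -0.111 (random lists from -0.041 to -0.020). The medians in sim were 0.032 and -0.092. Camera adjusted p was 0.00173 for both groups in rvWT, and adjusted p = 0.0851 with an estimated correlation; fry gave adjusted p = 0.0742 for the first group and 0.0013 for the second. Across 10662 genes the log2 differences of rvWT and of WT against null had a Pearson correlation of 0.174 and a Spearman correlation of 0.186 (0.115 and 0.160 for sim), and 56.2% of genes had the same sign.

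**Figure D3:**
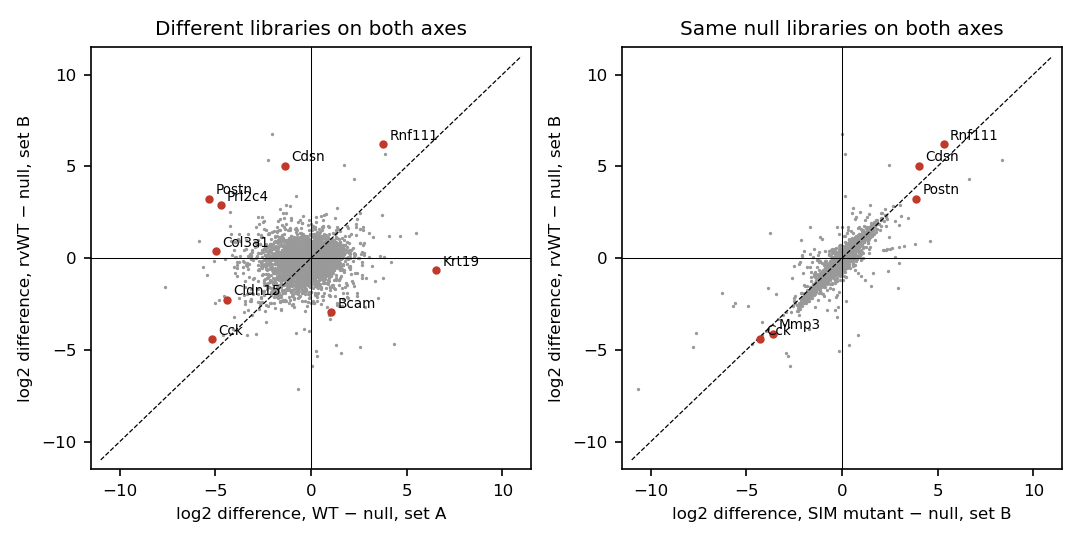
Log2 differences of rvWT minus null, with 1 point per gene, against those of WT minus null (left, no library on both axes) and of SIM mutant minus null (right, the same null libraries on both axes); the dashed line marks equal values. The Pearson correlation across genes is 0.174 on the left, where Postn, Cdsn and Krt19 lie on opposite sides of 0, and 0.864 on the right, where 0.632 came from simulated unchanged lines.

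Wild-type and SIM-mutant Arkadia were compared directly in the reconstituted lines, to find genes whose level depends on that motif. Nov (CCN3), a secreted matricellular protein, was lower in rvWT, at 47.1 FPKM against 118 in sim (log2 difference -1.33 ± 0.05 SE, n = 3 each, limma adjusted p = 0.0046). The growth factor genes and modulators Igfbp3 (-1.02), Igf2 (-0.95) and Sfrp1 (-0.85) and the matrix genes Tnn (-0.91) and Lum (-0.81) were lower too, as were Car2 (-0.85), Tnfaip3 (-0.74) and Rhbdl3 (-0.71). Prl2c2 (1.60 ± 0.09 SE, adjusted p = 0.0132) and Prl2c5 (1.49), which can share reads, were higher in rvWT, with Cdsn (0.99), osteopontin Spp1 (0.98), Igfbp6 (0.83), Il1rl1 (0.81), Trmt1 (0.58), Psca (0.57) and Snord87 (6.76). The call of Snord87 is uncertain: it was listed at 0 in sim, yet within null of set A it also stood at 254.3 FPKM at 0 h and at 0 at 4 h. Rnf111 itself was 0.90 ± 0.06 (SE) higher in rvWT (adjusted p = 0.0167), so the lines differ in the amount of Arkadia mRNA as well as in its motif. Of 10958 genes, 54 passed, 15 higher and 39 lower in rvWT, with 1818 at an unadjusted p under 0.05. The count was 8, 4 and 10 without rvWT 0, 1 and 4 h, 1, 2 and 10 without sim 0, 1 and 4 h, and 4 without null 0 h or null 1 h of set B.

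Extracellular matrix genes were lower in rvWT than in sim in 4 of 34 cases and higher in 0 (6 and 4 adjusted over the list alone), with Postn at -0.64, Col12a1 at -0.61 and Col11a1 at -0.58; camera did not call the list, while fry pointed down (adjusted p = 0.0445), 1 of 2 lists it called. Of 19 contractile genes 1, Actg2 (-0.67), was lower, or 5 adjusted over the list alone. The 23 receptors, SMADs and ligands held 0 called genes (1 higher and 4 lower adjusted over the list alone), and the 22 interferon response genes, the Hox genes and the early TGFβ targets held 0 as well, as did the Polycomb subunits and SUMO pathway genes (0 for each of these adjusted over the list alone). Among cartilage and bone markers Spp1 (0.98) was higher. Camera called 8 of 25 lists at the preset correlation, and which lists these were is not given here. It called 0 with an estimated correlation, where the lowest adjusted p = 0.372.

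The response to TGFβ at 1 h was measured in all 5 series, of which all but WT are null cells or derived from them. Snai1, a transcription factor of epithelial-mesenchymal transition, rose by 2.95 ± 0.09 (SE, limma adjusted p = 5.71e-08), from a mean of 15.8 to 128 FPKM over 5 series. The inhibitory SMAD gene Smad7 (2.04 ± 0.07 SE, adjusted p = 9.44e-08) and Junb (2.52 ± 0.15 SE) rose in each series. The growth factor genes Pdgfb (2.13) and Hbegf (2.00), the transcription factors Dlx2 (2.08) and Bhlhe40 (1.99), Rasl11b (2.07) and Spsb1 (1.95) rose as well. The chemokine Cxcl1 (-2.69 ± 0.21 SE, adjusted p = 3.67e-05), Adamts1 (-2.29), Osr1 (-1.19), Txnip (-1.17), Cebpd (-1.17), the signalling inhibitor Spry2 (-1.16), Rnd3 (-1.09), Cdc42ep3 and Cited2 (-0.94) fell. Arrdc1 (-1.93) fell too, with values close to 0 in several 1 h libraries. Of 11045 genes 658 passed, 436 up and 222 down, and 84 changed by at least 1 on the log2 scale. The count was 417 without rvWT 0 h, 438 without rvWT 1 h, 422 without sim 0 h, 401 without null 0 h of set B and 400 without null 1 h of set B. Set A alone gave 12 genes, and set B alone, which holds no WT library, 461 (372 up, 89 down).

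At 1 h early TGFβ targets rose in 14 of 21 cases and fell in 0 (18 and 0 adjusted over the list alone), with Pmepa1 at 1.58. For early TGFβ targets camera gave adjusted p = 2.79e-31, and adjusted p = 0.000694 with an estimated correlation. BMP and Id targets rose in 7 of 12 cases and fell in 0 (11 and 0 adjusted over the list alone), with the inhibitory SMAD gene Smad6 at 1.94, the BMP antagonist Nog at 1.88 and Id4 at 1.24. For BMP and Id targets camera gave adjusted p = 6.35e-14, and adjusted p = 0.0257 with an estimated correlation. In the WT series, however, Id1 and Id3 hardly changed and Id2 was lower at 1 h than at 0 h. The average rise of these Id genes thus rests on null cells and lines derived from them. Immediate early genes rose in 8 and fell in 1 of 20 cases (12 and 2 adjusted over the list alone; 7 and 0 with quantile normalization), with Nr4a1 at 1.49 and Klf4 at 0.94. For immediate early genes camera gave adjusted p = 3.77e-09, and adjusted p = 0.375 with an estimated correlation. Hox genes rose in 4 of 18 cases (6 adjusted over the list alone), with Hoxb2 at 0.60. For Hox genes camera gave adjusted p = 2.60e-07, and adjusted p = 0.375 with an estimated correlation. Of the 34 matrix genes 0 passed, although camera called the list (adjusted p = 0.0247; adjusted p = 0.375 with an estimated correlation). Of 23 receptors, SMADs and ligands 2 rose, Smad3 (0.31) and Ltbp3 (0.27), or 6 with 1 falling adjusted over the list alone, and of 22 cytokines, chemokines and proteases 4 rose and 1 fell, or 5 and 1. For these 2 lists camera gave adjusted p = 0.0356 and 0.0166, and adjusted p = 0.375 and 0.25 with an estimated correlation.

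At 4 h Pmepa1 rose by 2.31 ± 0.08 (SE, limma adjusted p = 3.35e-07, 4 series) and the matricellular Ctgf by 3.07 ± 0.38 (SE). The scavenger receptor Olr1 (2.69), Kctd11 (2.65), Pdgfb (2.64), Egr2 (2.57), Hbegf (2.39), the gelatinase Mmp9 (2.33) and the cytokine Lif (2.28) rose too. Id2, an inhibitor of differentiation whose level at 1 h lay above that at 0 h in 4 of the 5 series, fell by 2.28 ± 0.34 on the log2 scale (SE, adjusted p = 0.000893). Rasl11a (-2.08), Adamts1 (-1.86), Atoh8 (-1.82), Cxcl1 (-1.71) and Sdpr (-1.60) fell as well. Falls of Nxt2 (-2.23), Timeless (-2.06), Fam13c (-1.91) and Wash (-1.76) rest on values near 0 in some 4 h libraries. Of 11045 genes 4307 passed, 1317 up and 2990 down; the split was 1899 up and 1815 down with median-ratio scaling and 1667 up and 1986 down with quantile normalization. Changes of at least 1 on the log2 scale were seen in 166 genes. The count was 2740 without rvWT 0 h and 2658 without sim 4 h. Set A alone gave 16 genes, and set B alone, which holds no WT library, 4266 (1398 up, 2868 down).

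Early TGFβ targets rose in 19 and fell in 1 of 21 cases at 4 h, the same adjusted over the list alone. For early TGFβ targets camera gave adjusted p = 1.43e-17, and adjusted p = 0.00548 with an estimated correlation. Extracellular matrix genes rose in 20 and fell in 3 of 34 cases, the same adjusted over the list alone, with Thbs1 at 1.41, Col5a1 at 0.77 and the collagen-modifying enzyme Plod2 at 0.71. For matrix genes camera gave adjusted p = 1.84e-08, and adjusted p = 0.0267 with an estimated correlation. Contractile genes rose in 13 and fell in 0 of 20 cases (14 and 0 adjusted over the list alone), with the fibronectin receptor subunit Itga5 at 1.56 and Actn1 at 0.59. For contractile genes camera gave adjusted p = 1.66e-10, and adjusted p = 0.0211 with an estimated correlation. Cytokines, chemokines and proteases rose in 14 and fell in 3 of 22 cases, the same adjusted over the list alone, with Ccl2 at 1.97 and Tnfaip3 at 1.23. For cytokines, chemokines and proteases camera gave adjusted p = 8.09e-07, and adjusted p = 0.0192 with an estimated correlation. Immediate early genes rose in 15 and fell in 1 case (16 and 1 adjusted over the list alone), with Cyr61 at 1.30 and Ier2 at 1.28. For immediate early genes camera gave adjusted p = 7.08e-10, and adjusted p = 0.212 with an estimated correlation. P53 targets rose in 6 and fell in 2 cases (7 and 2 adjusted over the list alone; 7 and 1 after median-ratio scaling), with Plk2 at 1.05. For p53 targets camera gave adjusted p = 0.00757, and adjusted p = 0.0974 with an estimated correlation. Imprinted genes fell in 9 and rose in 2 of 13 cases (10 and 2 adjusted over the list alone), with Peg3 at -0.80 and Peg10 at -0.73, and the neural markers Tubb3 (0.85) and Ncam1 (0.92) rose, with 3 up and 1 down adjusted over the list alone. For imprinted and neural genes camera gave adjusted p = 0.0488 and 0.0368, and adjusted p = 0.12 for both with an estimated correlation. BMP and Id targets fell in 6 and rose in 1 of 12 cases, the same adjusted over the list alone, with Id4 at -0.74, and camera did not call them. Nor did it call fibroblast markers (1 up and 4 down of 10, the same adjusted over the list alone) or epithelial markers (2 up and 1 down of 4, or 3 and 1). Fry pointed down for BMP and Id targets and for fibroblast markers (adjusted p = 0.00467 each) and did not call epithelial markers (0.127). Mesothelial markers fell in 7 and rose in 1 of 14 cases, with a median of -0.225 (matched random lists -0.215 to 0.067). They were listed after several values had been seen, so the random lists are no test of them.

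At 16 h, measured in WT and null of set A alone, the fibrillar collagen gene Col11a1 rose by 2.296 ± 0.08 (SE, limma adjusted p = 3.72e-07, 2 series), and the cysteine protease Ctsw by 3.72 ± 0.21 (SE, adjusted p = 6.86e-06). The chemokine Ccl17 (3.20), Mmp9 (2.74), Ctgf (2.72), Csdc2 (2.54), Krt14 (2.46) and Pdgfb (2.39) rose too. The surface antigen Ly6a (-2.26 ± 0.15 SE, adjusted p = 1.18e-05), the helicase gene Ddx4 (-2.10), the imprinted gene Mest (-2.08), Cxcl1 (-2.30) and Prl2c4 (-2.08) fell. The mitotic genes Psrc1 (-2.38) and Troap (-2.12) fell, with values near 0 in the WT 16 h library. Of the small RNA genes Snord23 (5.34) rose, and Snord4a (-7.68), Snord88c (-4.83) and Mir1940 (-3.20) fell. Of 11045 genes 2139 passed, 755 up and 1384 down; the split was 1047 up and 946 down with median-ratio scaling and 1020 up and 988 down with quantile normalization. At least 1 on the log2 scale was reached by 232 genes, and the count was 1264 without null 0 h of set A, 640 without null 16 h, and 245 from set A alone.

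Matrix genes rose in 23 and fell in 2 of 34 cases at 16 h (24 and 3 adjusted over the list alone), with Tnc at 1.49, Loxl2 at 0.97 and Col5a2 at 0.83, and early TGFβ targets rose in 14 and fell in 1 of 21 cases (15 and 1 adjusted over the list alone), with Pmepa1 at 2.12. For both lists the camera adjusted p was 3.67e-15, and adjusted p = 0.00723 with an estimated correlation. Contractile genes rose in 14 and fell in 0 of 20 cases, the same adjusted over the list alone, with Tagln at 1.34, the smooth muscle actin Acta2 at 1.08 and Tpm1 at 0.85. For contractile genes camera gave adjusted p = 2.23e-13, and adjusted p = 0.0104 with an estimated correlation. Of 22 cytokines, chemokines and proteases 12 rose, such as Mmp2 (1.03) and Mmp14 (0.79), and 5 fell, such as Mmp13 (-1.50), the same adjusted over the list alone. For cytokines, chemokines and proteases camera gave adjusted p = 6.65e-05, and adjusted p = 0.0289 with an estimated correlation. The neural markers Tubb3 (1.17) and Ncam1 (1.63) rose among 4 tested, or 3 adjusted over the list alone. For neural markers camera gave adjusted p = 0.00268, and adjusted p = 0.0453 with an estimated correlation. Cell cycle genes fell in 11 of 28 cases and rose in 0 (18 and 0 adjusted over the list alone; 5 and 0 after median-ratio scaling), with Ccnd1 at -0.61 and Pcna at -0.33. For cell cycle genes camera gave adjusted p = 6.65e-05, and adjusted p = 0.495 with an estimated correlation. Cholesterol synthesis genes rose in 3 of 21 cases, the same adjusted over the list alone, with Insig1 at 0.41, and immediate early genes in 2, or 1 adjusted over the list alone, with Cyr61 at 0.99 (camera adjusted p = 2.39e-05 and 0.0417; adjusted p = 0.459 and 0.617 with an estimated correlation). Camera called neither fibroblast markers, 0 up and 4 down of 10 (1 and 5 adjusted over the list alone), nor epithelial markers, 3 up and 1 down of 4 (the same adjusted over the list alone); fry pointed down for the former (adjusted p = 0.000168) and did not call the latter (0.485). Mesothelial markers fell in 9 and rose in 1 of 14 cases, with a median of -0.517 (matched random lists -0.203 to 0.078, again no test of a list written after values had been seen). Over the line and TGFβ comparisons and the differences in response, camera made 60 list calls, of which 11 held with an estimated correlation, 2 at 1 h, 4 at 4 h and 5 at 16 h. Fry called 81 lists, among them 2 at 1 h, 12 at 4 h and 11 at 16 h, and 0 for the differences in response.

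**Figure D4:**
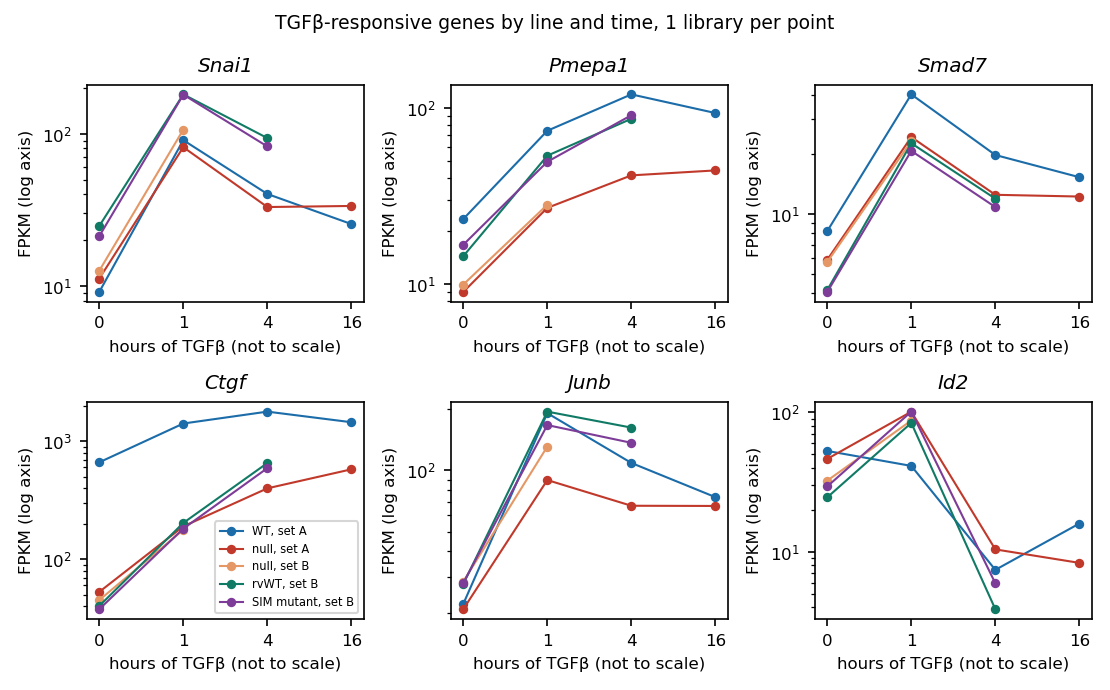
FPKM (log axis) of Snai1, Pmepa1, Smad7, Ctgf, Junb and Id2 against hours of TGFβ (not to scale), with 1 library per point and a line joining the libraries of a series. Snai1 was higher at 1 h than at 0 h in every series, from 9.17 to 90.5 FPKM in WT and from 11.2 to 81.4 FPKM in null of set A, and Id2 was lower at 4 h than at 0 h in each series with a 4 h library.

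Whether the response to TGFβ differs with Arkadia was tested by the interaction of treatment with Arkadia status. Mir704 passed for wild-type Arkadia against null (limma adjusted p = 0.000381), 1 of the genes tested, with 350 at an unadjusted p under 0.05. Zfand2b and Crlf2 passed for sim against null (adjusted p = 0.0124 each), with 386 at an unadjusted p under 0.05, and Mir704 (adjusted p = 0.00176), Zfand2b (0.00604) and Crlf2 (0.0271) for wild-type Arkadia against sim, with 318. Each rests on values at 0 h. Mir704 was at 41.5 FPKM in WT 0 h and 95.5 in rvWT 0 h and listed at 0 in the other libraries, Zfand2b was at 0.0733 FPKM in sim 0 h against 4.23 to 11.03 elsewhere, and Crlf2 at 0.488 against 3.03 to 6.70. The comparisons with sim cannot be fitted without sim 0 h, so these calls were not checked without that library. For wild-type Arkadia against null the count was 11 without WT 0 h, 4 without WT 16 h or null 16 h, and 2 without rvWT 0 h or null 0 h or 1 h of set B. For sim against null it was 0 without WT 4 h, null 0 h of set A or sim 4 h, 1 without sim 1 h, 4 without null 4 h or rvWT 4 h, and 5 without null 0 h or 1 h of set B. For wild-type Arkadia against sim it was 11 without WT 0 h, 5 without WT 16 h or null 16 h, and 1 without sim 4 h. As groups, camera called 4 lists for wild-type Arkadia against null, none with a gene that passed: cell cycle (higher, adjusted p = 0.000682), cholesterol synthesis (lower, 0.00043), interferon response (lower, 0.0287) and hypoxia and glycolysis (higher, 0.0287). For wild-type Arkadia against sim it called immediate early genes (lower, adjusted p = 0.000515) and cholesterol synthesis (lower, 0.044). With an estimated correlation all had an adjusted p of 0.844 and 0.963 in these 2 comparisons, so 0 of the 6 calls held.

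Single libraries of WT and null in set A, 1 per time and hence without a replicate check, gave the size of the response by gene. Pmepa1 went from 23.3 FPKM at 0 h to 74.5, 120 and 94.0 at 1, 4 and 16 h in WT and from 8.95 to 27.0, 41.4 and 44.2 in null, and in rvWT and sim it reached 87.2 and 91.3 FPKM at 4 h. Ctgf was at 663 FPKM in WT and 52.9 in null at 0 h, and at 1449 and 578 at 16 h. The fixed early target list had a median log2 response of 1.09 in WT and 1.19 in null at 1 h, 1.23 and 0.972 at 4 h, and 0.769 and 1.38 at 16 h. Taken gene by gene, the median of WT minus null was 0.079 at 1 h (95% of matched random lists from -0.084 to 0.069), 0.313 at 4 h (-0.077 to 0.117) and -0.118 at 16 h (-0.084 to 0.191), so at 1 h it has the opposite sign to the difference of the medians. In set B the medians were 1.25 in rvWT, 1.48 in sim and 1.11 in null at 1 h, and 1.35 in rvWT and 1.47 in sim at 4 h. The sim median at 1 h is the value of Sphk1, which went from 0.00011 to 1.785 FPKM there. In rvWT Sphk1 lay near 0 FPKM at 0 and 1 h, with a response of 0. The order of rvWT and sim at 1 h therefore depends on Sphk1. The null median of 1.19 at 1 h in set A is the value of Sphk1 too. Gene by gene the median at 1 h was -0.019 for rvWT minus null (random lists -0.062 to 0.059), 0.082 for sim minus null (-0.06 to 0.112) and 0.069 for rvWT minus sim (-0.107 to 0.049), and at 4 h 0.054 for rvWT minus sim (-0.124 to 0.075). For rvWT minus null at 1 h and rvWT minus sim at both times this is again opposite in sign to the difference of the medians. For 370 genes that rose at 1 h in set B, the median response at 1 h in set A was 0.535 in WT and 0.493 in null, with a gene-by-gene median of 0.033 (random lists -0.032 to 0.007; 0.0521 with a pseudocount of 0.1). For 1382 genes that rose at 4 h in set B, the median response in set A was 0.245 in WT and 0.260 in null at 4 h, and 0.134 in WT and 0.3304 in null at 16 h. The gene-by-gene median of WT minus null was 0.034 at 4 h (random lists 0.006 to 0.029), again opposite in sign to the difference of the medians, but 0.0206 with a pseudocount of 5 and 0.0045 with quantile normalization. It was -0.167 at 16 h (0.032 to 0.063), as a description of these libraries. Genes taken from set B were chosen in null cells and lines derived from them, at 4 h in rvWT and sim alone. That choice can favour a larger response in null than in WT, and random lists matched on expression do not carry it. For 2778 genes that fell at 4 h in set B, the medians were -0.209 in WT and -0.212 in null at 4 h, and -0.107 and -0.304 at 16 h, with gene-by-gene medians of 0.003 (random lists 0.002 to 0.018) and 0.196 (0.044 to 0.066). The 4 h value turned to -0.00626 with a pseudocount of 0.1, -0.00451 with median-ratio scaling and -0.00612 with quantile normalization, and the 16 h value was 0.129 with a pseudocount of 5.

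The rule for the largest single-library differences in response between WT and null took 20 genes at each time. At 4 h 18 of them were small RNA genes and all 20 had a value under 0.1 FPKM in a library; at 16 h these numbers were 19 and 20. Among genes at 1 FPKM or more in all 4 libraries, a choice made after seeing the data, the rise at 4 h was larger in WT for the transcription factor Runx1 (WT minus null 1.82) and Tnfaip6 (1.81). The protease inhibitor Timp1 (1.74) and Lzts2 (2.23) rose in WT and were lower at 4 h than at 0 h in null. The rise was larger in null for Mcam (-2.00), and Wisp2 (-2.03) rose in null and not in WT. At 16 h the rise was larger in null for Mcam (-2.69), Ctgf (-2.30) and Hbegf (-1.86). The metallothionein gene Mt2 fell by 2.14 in null and rose by 0.42 in WT, Gas1 fell by 2.08 in null and by 0.21 in WT, and Mt1 fell in null too, with a difference of 1.88. These values are log2 differences between single libraries, without a test.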

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

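The interaction tests, the count after median-ratio scaling and the effect of scaling on the interferon genes were set before their results were seen; the use of that count and the other tests of the breadth of the WT against null difference, its splits included, and the tests of infection and restored Arkadia for the interferon genes, and of the mesothelial markers were chosen after the result was seen.

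Mir704, Zfand2b and Crlf2 stood out because a test of the interaction found their TGFβ response to differ with Arkadia status. The log2 difference in response was -5.96 ± 0.32 (SE) for Mir704 between wild-type Arkadia and null and -5.98 ± 0.38 (SE) between wild-type Arkadia and sim. For Zfand2b it was 3.42 ± 0.29 (SE) between sim and null and -3.44 ± 0.28 (SE) between wild-type Arkadia and sim, and for Crlf2 1.81 ± 0.16 (SE) and -1.52 ± 0.16 (SE). The 0 h values behind all of them come from 1 or 2 libraries each.

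Of 30 named genes tested in both comparisons, 11 differed from null one way in every pair of WT and the opposite way in every pair of rvWT; the difference between these comparisons was not tested. The log2 differences in WT and in rvWT were 6.56 and -0.66 for Krt19, 4.32 and -4.71 for Mir3061 and 1.04 and -2.97 for Bcam. They were -5.84 and 0.95 for Ptn, -5.33 and 3.24 for Postn, -4.98 and 0.37 for Col3a1, -1.61 and 2.67 for Col6a3, -1.36 and 5.04 for Cdsn and -1.09 and 2.85 for Trib3. Mir3061 scattered within null, at 5.72 ± 11.45 FPKM in set A (SD, n = 4) and 25.5 ± 6.16 in set B (SD, n = 2), so its reversal is uncertain. The paralogs Prl2c2 (-4.22 and 2.53) and Prl2c4 (-4.72 and 2.89) can share reads.

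The WT against null difference reached 7411 genes, and 1 of 32 splits of the 8 libraries, the real one, called as many (the highest of the others called 6; 3 of 35 splits could not be estimated). These splits mix libraries across times, which the fit keeps as a block, and exchanging WT and null within a time gives 8 splits, too few for a share under 0.05 (7411 in the real one; 0 in the highest of the others). Against scaling of the libraries as its source, 7241 genes were called after median-ratio scaling. For loss of Arkadia as the whole and reversible source, the slope of rvWT minus null on WT minus null was 0.123 ± 0.0181 (SD over resampled genes) over 1218 genes. It ran from 0.110 to 0.132 with each of the 16 libraries left out, where full reversal gives a slope near 1. On balance these genes thus lay far from the WT level in rvWT. However, rvWT was infected without an empty-retrovirus control and held Rnf111 at 112.8 FPKM against 14.8 in WT, so the slope does not decide on this source. Different embryos of origin stay open, since Xist differed by -3.92 between these lines and each line is represented by its own cells, so embryo and Arkadia status cannot be told apart for the genes of this comparison, and an irreversible effect of losing Arkadia was not tested.

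Interferon response genes were higher than null in 19 of 22 cases in both reconstituted lines. Against scaling of the libraries as the source, the smaller of both medians was 0.969 after median-ratio scaling. Infection with the retrovirus is a candidate explanation: the list's median differed by -0.15 between rvWT and sim, beside rises of 0.91 and 1.08, but sim also carries Arkadia, and no line with an empty retrovirus was used here. Restored Arkadia stays open as well, because the list's median of -0.57 in WT against null goes the other way, yet the WT cells may differ from null in origin, so that comparison does not decide.

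Mesothelial markers, a list of 20 genes of which 15 were in the table and 3 were also in the epithelial list, were lower than null in 13 of 13 tested cases in rvWT (median -2.23, matched random lists -0.25 to 0.18) and in sim (median -1.94). Because the list was written after several of its values had been seen, the random lists given for it are a description and no test. Mean levels were 486.8 FPKM in null of set B, 71.8 in rvWT and 97.7 in sim for Upk3b, 115.4, 20.1 and 24.3 for Msln, and 100.8, 19.7 and 21.8 for Upk1b. A smaller share of mesothelium-like cells in the infected cultures may account for part of this. The markers ran from -0.30 (Bnc1) to -2.77 (Aldh1a2) in rvWT. A marker that the remaining cells also express would fall less, so unequal falls do not decide and this explanation stays open. Wild-type Arkadia as such stays open too: the median was -0.55 in WT against null, with 4 markers higher, such as Wt1 (1.79) and Upk1b (1.66), and 9 lower, and the median of rvWT minus sim was -0.298 (matched random lists -0.089 to 0.079), with 2 of 13 markers lower and 0 higher. Since the markers go both ways in WT, and rvWT also holds more Rnf111 mRNA than sim, these values do not decide.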

How the results depend on the processing

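The alternatives without small RNA genes, without these and the genes that drop out, and without the 16 h libraries were chosen after the data had been seen. For the genes named in the text 11027 combinations of 581 gene results and settings were run: 10396 kept their direction and side of the threshold, 631 kept the direction and no longer passed (135 gene results, most often without the null 0 h or 1 h library of set B, 76 and 74 times), and 0 turned around. The comparisons differed: for rvWT against sim 172 of 393 combinations no longer passed, touching 24 of 25 gene results, against 10 of 1679 combinations for WT against null. No paired analysis was possible by replicate number, because each line has 1 library per time within a set. Only null at 0 and 1 h has a further number, which marks its set B library and pairs it with no other line. The main fits had the time or the series as a block. The table held 0 duplicated symbols, so the alternative of keeping duplicates was not run, and 16 h could not be fitted from set B. Depth is unknown, so its effect on low genes could not be measured.

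With a log2 threshold of 1 the counts were 1336 for WT against null, 651 for rvWT, 555 for sim, 6 for rvWT against sim, and 84, 166 and 232 for TGFβ at 1, 4 and 16 h, since smaller changes no longer count. Set A alone gave 12, 16 and 245 genes for TGFβ and 9 for the response of wild-type Arkadia against null. Set B alone, with as many libraries, gave 461 genes for TGFβ at 1 h and 4266 at 4 h, and the cause of this gap was not tested. Without the time term the counts were 2200 for rvWT, 1777 for sim and 7 for rvWT against sim. That last count was 93 with robust variances, 17 in a fit over all 16 libraries, 10 from 0 and 1 h, 83 without small RNA genes and 89 without these and the genes that drop out; the cause was not tested.

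For the response of wild-type Arkadia against null the count was 4 from 1 h alone, 8 from 4 h alone, 0 without small RNA genes, 0 without these and the genes that drop out, and 4 without 16 h (350 genes had an unadjusted limma p under 0.05). For sim against null it was 5 with a pseudocount of 0.1, 0 with 5, and 1 with a minimum of 5 FPKM or without small RNA genes and those that drop out. For wild-type Arkadia against sim it was 8 and 1 with these pseudocounts, 1 with that minimum, 1 without small RNA genes and those that drop out, and 5 without 16 h. The cause was not tested. The correlation of rvWT with WT differences moved from 0.174 to 0.196 without small RNA genes and 0.198 without these and the genes that drop out (bootstrap SD 0.0207). Of 60 list calls 11 held with an estimated correlation.

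The WT minus null difference in response was 0.0521 for genes rising at 1 h with a pseudocount of 0.1. For genes rising at 4 h it was 0.0206 with a pseudocount of 5, 0.0241 with median-ratio scaling and 0.0045 with quantile normalization at 4 h, and -0.139, -0.176 and -0.205 at 16 h. For genes falling at 4 h it was -0.00626 with a pseudocount of 0.1, -0.00451 with median-ratio scaling and -0.00612 with quantile normalization at 4 h, against 0.003 as reported, and 0.215, 0.129 and 0.180 at 16 h with pseudocounts of 0.1 and 5 and quantile normalization. The cause was not tested.

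With each library left out in turn the counts ran from 6266 to 7343 for WT against null, 1946 to 4249 for rvWT, 1581 to 3854 for sim and 1 to 10 for rvWT against sim. They ran from 400 to 815, 2658 to 4779 and 640 to 3026 for TGFβ at 1, 4 and 16 h, and from 1 to 11, 0 to 5 and 1 to 11 for the differences in response of wild-type Arkadia against null, sim against null and wild-type Arkadia against sim. Each library of a fit was left out, except sim 0 h for the comparisons of response with sim, which cannot be fitted without it. A lone library was assumed to vary like the others. The alternatives not given here kept their counts within 1.5 times.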

Other observations

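The splits of the rvWT and sim libraries were a test chosen after the result was seen, as was the comparison of Id and metallothionein genes; the splits for the TGFβ response and for its differences with Arkadia status were set before, and those within a time or series after.

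The Id genes, which encode inhibitors of basic helix-loop-helix transcription factors, were chosen after their values were seen. Id1 stood at 131 FPKM at 0 h and 124 at 1 h of TGFβ in the WT libraries, against 110 and 258 in null of set A, 147 and 362 in null of set B, 70.0 and 268 in rvWT and 67.6 and 295.0 in sim. Id3 went from 169 to 173 FPKM in WT, against 168.0 to 440.5 in null of set A, 231 to 617 in null of set B, 224.5 to 690.1 in rvWT and 213 to 763 in sim. Id2 went from 52.8 to 41.3 FPKM in WT, against 46.3 to 101 in null of set A, 24.5 to 84.0 in rvWT and 29.4 to 101 in sim, and it was higher at 1 h in null of set B too. Over all series the rise at 1 h passed for Id1 (1.30 ± 0.25 SE, limma adjusted p = 0.0115) and Id3 (1.26 ± 0.30 SE, adjusted p = 0.0323) and did not for Id2 (1.13 ± 0.31 SE, adjusted p = 0.0605). The interaction over all times, which takes WT and rvWT together, did not pass for these genes (limma adjusted p = 0.997 each, wild-type Arkadia against null). It therefore does not test WT alone, and a difference at 1 h alone rests on a single WT library.

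The metallothionein genes Mt1 and Mt2, which bind zinc and other metals, were lower in WT than in null (-2.43 ± 0.36 SE, limma adjusted p = 0.00247, and -2.20 ± 0.44 SE, adjusted p = 0.00729). Mt1 stood at 24.5 FPKM in WT at 0 h, 184.3 in null of set A, 224 in null of set B, 166 in rvWT and 135 in sim. Mt2 stood at 9.44, 84.4, 75.1, 24.4 and 21.4 FPKM in the same libraries.

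Other splits of the libraries were set beside the real one. For TGFβ at 1 h, 1 of 100 splits, the real one, called as many genes (658; 36 in the highest of the others). At 4 h 1 of 100 splits called as many (4307; 2667 in the highest of the others). Among the 4 splits that exchanged all 4 treated libraries, near mirror images of the real one, the calls were 2667, 2635 and otherwise 0. Those that kept 1 to 3 treated libraries called at most 1. These splits mix libraries across series, which the fit keeps as a block, so the share expected of them in advance does not settle chance. Exchanging 0 h with the treated library within a series gives 16 splits at 1 h (0 in the highest of the others) and 16 at 4 h (2667), too few for a share under 0.05. For rvWT against sim 1 of 10 splits called as many (54; 14 in the highest of the others), and 10 splits are too few for a share under 0.05, as are the 4 within a time (0 in the highest of the others). For the response of wild-type Arkadia against null 5 of 15 assignments called as many (1; 2 in the highest of the others), and 15 are too few as well. For the response of sim against null 17 of 30 assignments called as many (2; 11 in the highest of the others), and for wild-type Arkadia against sim 11 of 30 (3; 11 in the highest of the others), so chance cannot be excluded for either.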
